A study of Homo sapiens with 12 samples.

How the data were processed

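Gene expression was measured by polyA RNA sequencing in 12 libraries of HCT116 cells, 3 for each of the mCherry, CR3, scramble and reverse constructs. Per the labels' protocols, cells were grown in DMEM with fetal calf serum, treated with doxycycline at 1 ug/ul as the labels write it (48 before extraction, with no unit given), and libraries were made with a stranded TruSeq kit from RNeasy-extracted RNA. Groups and replicate numbers were taken from the sample titles.

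Per the submitters' processing notes, FastQC, Trim Galore, STAR, featureCounts, edgeR, DESeq2, Salmon, GATK and MultiQC were used with the GRCh38 build. Versions and settings, including the strand setting of the counting and the annotation release, are not given in the sources used here, so values of antisense and overlapping genes are uncertain. The deposited values are read counts per gene that the authors had divided by a size factor for each library, a unit found from the values themselves. They cover 63677 Ensembl identifiers. In the deposited table the decimal mark had been lost from every value of 1 or more, so that only the digits remained. A total of 18138 cells kept their mark.

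The counts were rebuilt before any test. In each library the worth of 1 read was found from the values, and every non-zero cell (265152 of them) was then a whole multiple of it at some power of 10, 100.0% within a tolerance of 1e-07. The power of each cell was chosen per gene by likelihood, using the group labels, so that libraries of a group lie close together while groups may differ. In 1664 cells (0.63%) another power was within a likelihood ratio of 20. Genes with such a cell were left out. Only cells of 1 read kept the mark, and with it hidden 98.41% of these were read correctly. On simulated data 99.916% of non-zero cells were recovered, and 96.46% of those of the 200 changed genes. Of 162 wrong cells, 60 were in genes above 100 reads, and 88.9% were marked ambiguous. Genes above 100 reads whose 3 counts in a group were all multiples of 10 numbered 14, 11, 16 and 12 in mCherry, CR3, scramble and reverse, where chance gives 11.2, 11.5, 11.3 and 11.2. A gene that fell by around 10-fold in 1 group can still be read as nearly unchanged, so the counts of large decreases are the less certain ones. Recomputed size factors were 0.961 to 0.967 of the deposited ones in all libraries, a constant that does not alter comparisons.

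Library totals ranged from 17431340 to 23566156 reads, and 32185 identifiers had no read in any library. Libraries of a group differed by more than sampling noise (chi-square over degrees of freedom 2.74 to 9.79), and each was treated as 1 sample. This spread does not show whether they came from separate cultures. Symbols and coordinates came from GENCODE release 29 on GRCh38 and a table of gene names. They matched 52526 identifiers, and 15787 of the 16164 tested ones.

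Tests were run in R 4.3.3 with limma 3.58.1, and the rebuilding and figures in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The design fixed before the data were examined planned a count test on TMM-scaled counts. Because the deposited values are not counts, the test was limma with a mean-variance trend on log2(normalized reads + 1), with the deposited size factors, so fold changes understate those of low genes. A model with the 4 groups was fitted to all 12 libraries. Genes needed at least 10 reads in at least 3 libraries. This kept 16164 genes, of which 731 had an ambiguous cell and 15433 were tested. P-values were adjusted by Benjamini-Hochberg within each comparison and called under 0.05, two-sided. A gene counts as changed in CR3 against all 3 groups if it passed in each comparison with the same sign. For genes with no reads in a group, the fold is given against a floor of 3 reads per library, as "at least". For 1 to 3 reads in a group, the ratio is given with an exact 95% counting interval.

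Also fixed before the data were examined were 36 gene lists, the comparisons, the rule for named genes and part of the alternatives. The rule took called genes with a mean of at least 1 CPM, a symbol that is not a clone name and libraries of both groups that do not overlap. It ranked them by log2 fold change, taking 12 in each direction for CR3 against all 3 groups, 10 for CR3 against mCherry and 5 for each other comparison, plus up to 4 members per list by p in CR3 against mCherry. Of the genes this rule picks, 1 is not reported here. Other members of the lists named in the text were picked after their values were seen. Lists were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data, and with fry, adjusting over the 35 lists with at least 5 tested members. The lists cover Wnt, MYC, p53, ATF4, NRF2, NF-kB, interferon, immediate early, YAP/TEAD, TGF-beta and hypoxia targets, and chaperones of the cytosol and ER, proteasome, glycolysis, cholesterol synthesis, nuclear and mitochondrial respiration genes. They also cover DNA replication, mitosis, histones, ribosomal proteins, ribosome biogenesis, Mediator, RNA polymerase II, elongation and BET coactivators, super-enhancer-associated genes, splicing factors, stress granules and senescence. Cell type lists hold intestinal, epithelial, mesenchymal, immune, endothelial and embryonic kidney (HEK293-type) markers.

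The testing step was checked on simulated counts for CR3 against mCherry with 15134 genes, 200 of them changed. It called 174 of these in the right direction. Of 25 genes each, it found 18 higher and 12 lower at 1.3-fold, 24 and 22 at 1.5-fold, 25 and 23 at 2-fold, and 25 and 25 at 4-fold. It also called 8 unchanged genes (0.05%). Overlaps of comparisons with shared libraries were set beside 100 simulations without effects. These drew new libraries with noise independent between genes, so hardly any call can arise and counts of 0 were bound to appear. The alternatives set beforehand were library size alone, looser and stricter filters on low counts, a replicate block, a fit on the compared groups only, a minimum fold of 1.5 and leaving out each library. Those chosen after the results were seen were TMM, pseudocounts of 0.5 and 5, voom, powers of 10 set without group labels, keeping ambiguous genes, and leaving out low genes or the CR3 libraries.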

Results

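HCT116 is an established human colorectal cancer line with epithelial features. Cells of 4 genotypes were treated with doxycycline, a drug widely used to switch on inducible constructs, and polyA RNA was sequenced from 3 libraries of each. The groups are named after their genotype. mCherry is a fluorescent protein, here the control, CR3 is a peptide that the submitters describe as disturbing condensates, and scramble and reverse are the names of 2 further constructs, whose sequences are not given in the sources used here. Condensates are membraneless assemblies of protein and RNA, among them those that gather coactivators at enhancers. All 12 libraries came from doxycycline-treated cells, so an effect of the drug alone cannot be read from them. Each library held between 17431340 and 23566156 reads assigned to genes, with a median of 21830 genes having at least 1 read. Levels are given as normalized reads, the read count divided by the library's deposited size factor, as mean ± SD over 3 libraries.

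The CR3 libraries stood apart from the other 9. The first principal component held 72.3% of the variance and placed the CR3 libraries between 88.8 and 91.5, whereas the other 9 lay between -33.2 and -27. The second component, with 6.6%, separated mCherry (-28.6 to -22.1) from scramble and reverse (9.6 to 14.3), and the third, with 6%, separated scramble (19.1 to 22) from reverse (-23.8 to -19.7). Pearson correlations across genes were 0.9921 to 0.9943 within a group, 0.9875 to 0.9902 between mCherry, scramble and reverse, and 0.9418 to 0.947 between CR3 and any of them. Genes are not independent replicates, so these values describe the libraries only. The powers of 10 were also chosen with the group labels, which can bring libraries of a group closer together.

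**Figure D1:**
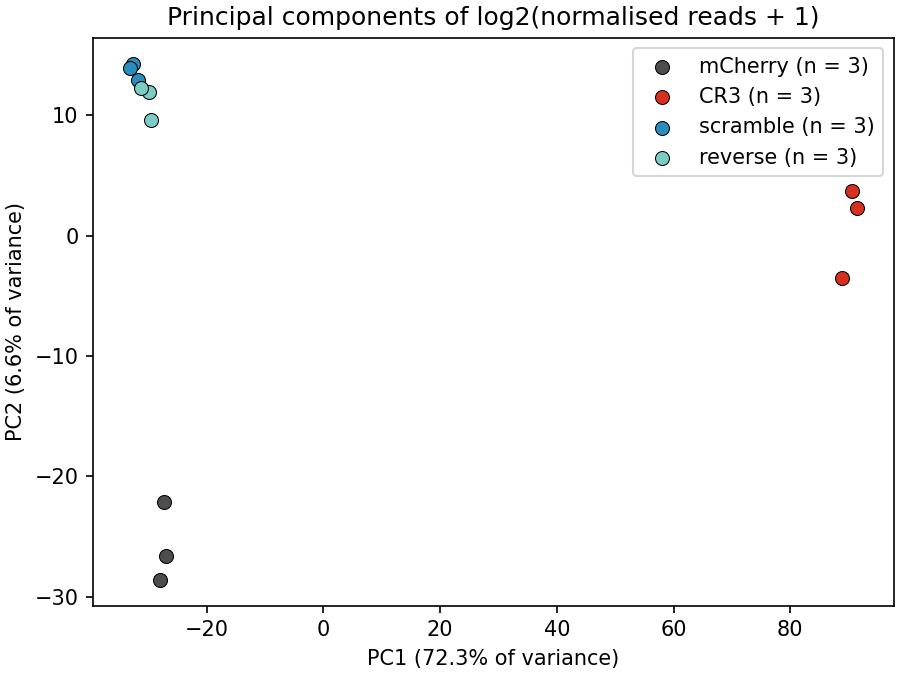
Each point is 1 library, placed by its scores on the first component (horizontal axis, 72.3% of variance) and the second (vertical axis, 6.6%), and colored by group with 3 libraries each. The 3 CR3 libraries sit between 88.8 and 91.5 on the horizontal axis, and the other 9 lie at -27 or below.

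The central comparison set CR3 against each of the other 3 groups, to ask what the peptide changes beyond the control protein and beyond the scramble and reverse constructs. CR3 cells carried many transcripts that were almost missing from the other cells, among them LAPTM5, LUZP4 and TLE4, and had lower levels of many abundant ones, among them PHLDB2, CD44 and MYC. Of 15433 genes tested with limma, 1696 were higher and 1729 lower in CR3 than in all 3 other groups, 3425 in all. In simulations with no effect the mean number was 0, but these hold hardly any calls by design. The increases were larger than the decreases. At least 2-fold changes in all 3 comparisons comprised 687 increases and 14 decreases, and the median of the smallest of the 3 log2 fold changes was 0.64 for the higher genes and -0.27 for the lower ones. Of the 687, 608 (88.5%) averaged fewer than 20 normalized reads over the 9 other libraries, 305 had 0 reads in all libraries of at least 1 other group, and 93 had 0 reads in all 9 other libraries. With groups at 0 set to a floor of 3 reads per library, all 687 stayed at least 2-fold higher, and the median of their smallest log2 ratio was 3.09. Together the 687 genes took 0.33% of the reads in CR3 and 0.03% elsewhere.

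LAPTM5 (ENSG00000162511, GRCh38 chromosome 1, 30732469 to 30757820), a lysosomal membrane protein best known from blood cells, reached 1326 ± 62.9 normalized reads in CR3 (n = 3). It had 1 read in the mCherry libraries, a ratio of 4100 with a counting interval of 736 to 162000, and its limma adjusted p was 1.3e-11 against mCherry, 3.67e-11 against scramble and 2.14e-11 against reverse. LUZP4 (ENSG00000102021, chromosome X, 115289727 to 115307556), a germline gene also expressed in tumors, stood at 393.1 ± 15.3 in CR3, at least 133-fold above mCherry and reverse, which had no reads. TLE4 (ENSG00000106829, chromosome 9, 79571773 to 79726882), a Groucho-type corepressor, reached 274.1 ± 16.5 and was at least 92.8-fold higher than in mCherry. CBS (ENSG00000160200, chromosome 21, 43053191 to 43076943), the enzyme that makes cystathionine, rose from 2.05 ± 1.92 in mCherry to 579.4 ± 35.1, with log2 fold changes of 7.74, 7.21 and 7.57 against mCherry, scramble and reverse. UCHL1 (ENSG00000154277, chromosome 4, 41256413 to 41268455), a deubiquitinating enzyme abundant in neurons, rose from 2.54 ± 2.25 to 493.5 ± 51.4. The basement membrane gene NID1 went from 2.80 to 554.3 ± 55.5, and IRS4, an adaptor of insulin receptor signaling, from 4.70 to 549.8 ± 54.2.

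PNMA8A (194.4 ± 21) was at least 65.8-fold above mCherry. BEX4, the extracellular matrix gene EMILIN3 and the glutathione transferase GSTM3 reached 267.1, 163.2 and 160.5 in CR3 with 1 to 3 reads in mCherry, ratios of 276 (94.2 to 1340), 506 (90.4 to 20000) and 495 (88.5 to 19600). XIST, the noncoding RNA of the X inactivation center, also belonged to the 12 largest increases under the rule for named genes, with log2 fold changes of 7.65, 9.21 and 7.83. The intervals and floors cover counting error only.

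**Figure D2:**
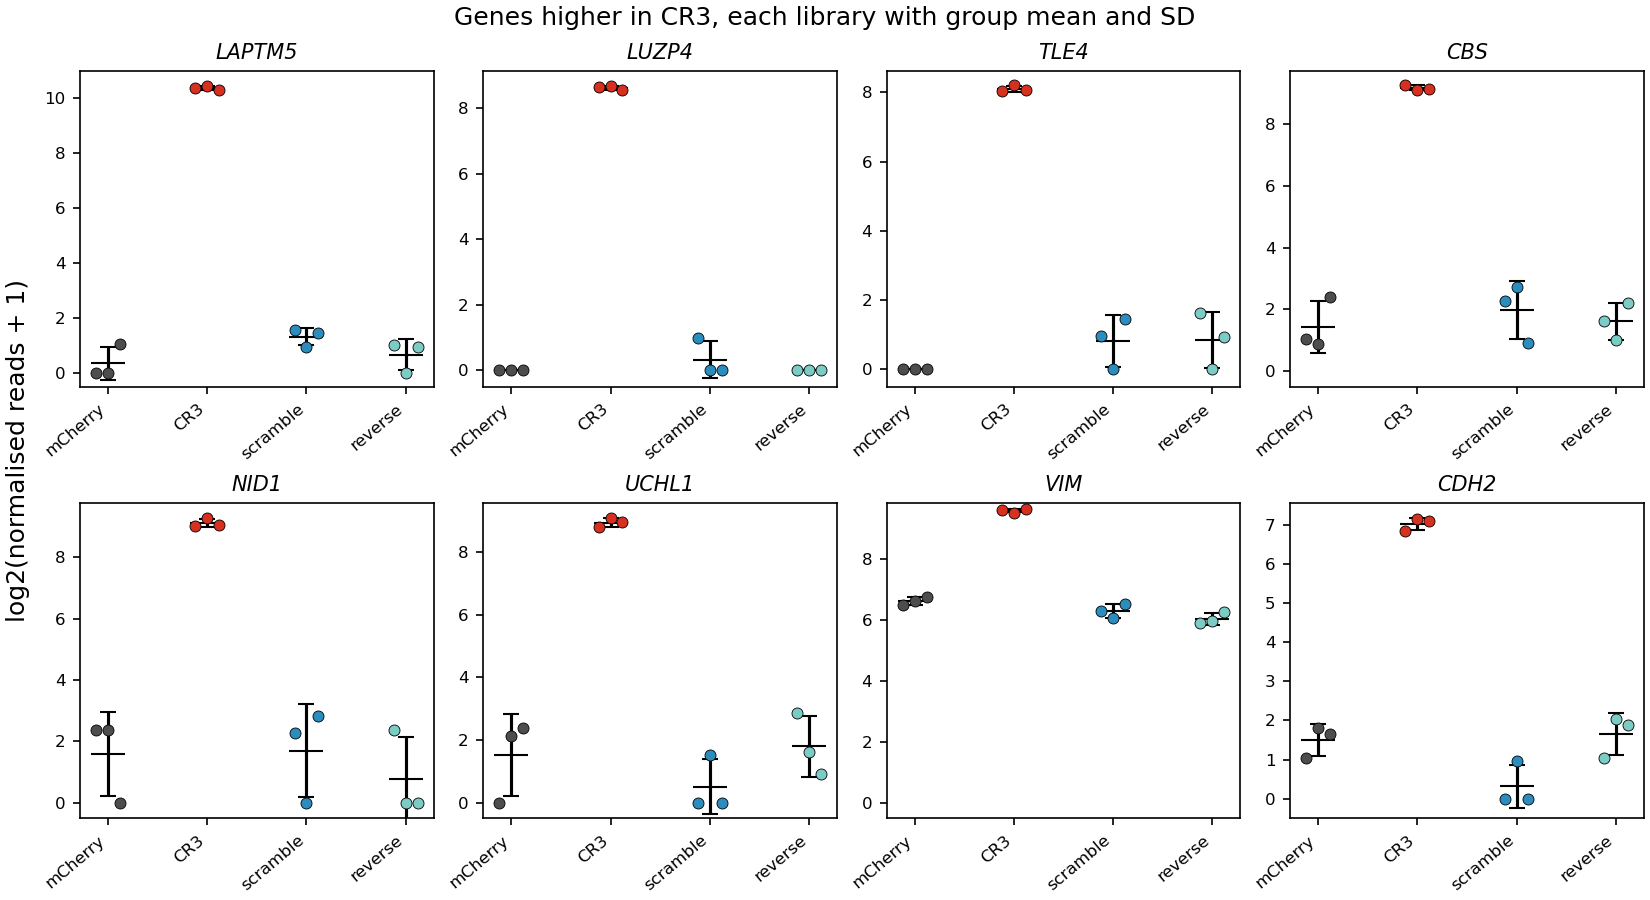
Points are single libraries, 3 per group, the bars give the group mean and SD, and the vertical axis gives log2(normalized reads + 1) for genes higher in CR3, a different range in each panel. LAPTM5 averages 1326 and LUZP4 393.1 in CR3, whereas both average below 2 in each of the other groups.

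Among genes that fell, most changed by less than 2-fold. The 14 genes lower by at least 2-fold in all 3 comparisons did not meet the rule for named genes, which needs at least 1 CPM on average, a gene symbol and no overlap between libraries, and those named in this paragraph are the 12 largest decreases that did. PHLDB2 (ENSG00000144824), which anchors microtubules at the cell cortex, fell from 3170 ± 189 normalized reads in mCherry to 1571 ± 49.8 in CR3, with log2 fold changes of -1.01, -0.85 and -0.96 against mCherry, scramble and reverse and a limma adjusted p of 1.1e-09 in the first. The sodium channel subunit SCNN1A went from 1369 ± 174 to 690.3 ± 130, the adhesion receptor ADGRF1 from 498.9 to 268.8, the growth factor carrier FGFBP1 from 76.6 to 42.0, and the organic anion exporter ABCC2 from 2495 to 1431. LAMA2, a laminin chain, had log2 fold changes of -1.18, -1.40 and -0.79, and the secreted ligand WNT16 of -0.84, -0.77 and -0.91. ENC1, an actin-binding protein, fell from 2388 to 1296, and the lincRNA LNCAROD from 287.7 to 130.8 ± 20.3. The pseudogenes CDC20P1, HMGB1P6 and PTMAP2 were also among those 12. Their reads may be shared with CDC20, HMGB1 and PTMA, so their values are uncertain.

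**Figure D3:**
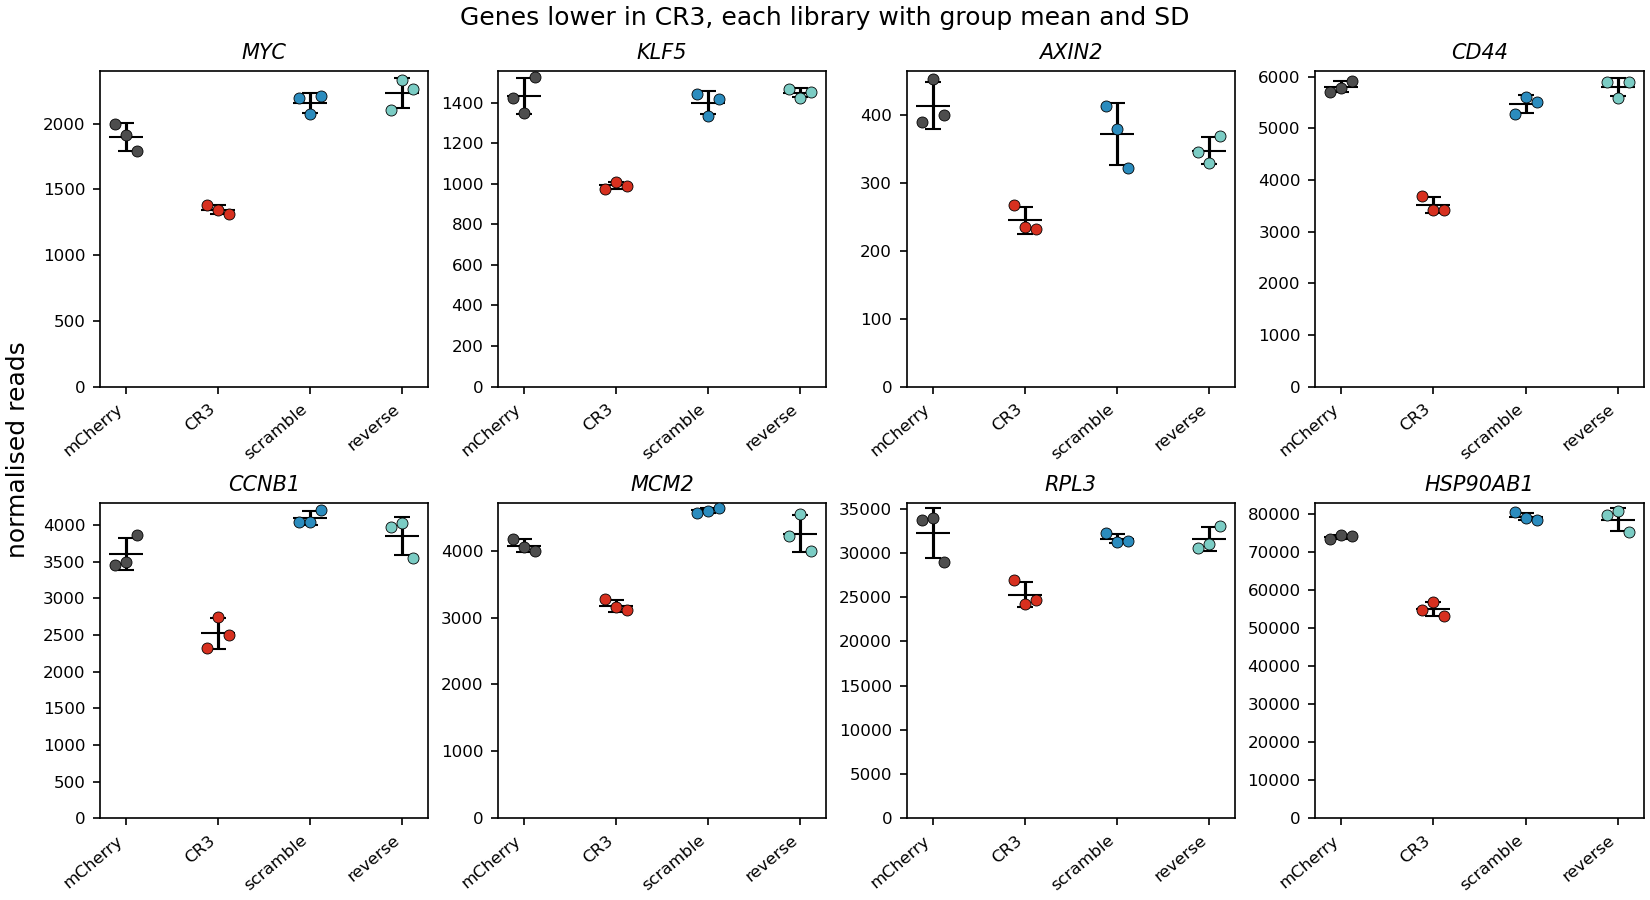
Points are single libraries, 3 per group, the bars give the group mean and SD, and the vertical axis gives normalized reads for genes lower in CR3 than in all 3 other groups. CD44 averages 3508 in CR3 against 5807 in mCherry.

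Genes of cell division fell together. Of the 24 tested genes of the G2/M and mitosis list, 23 were lower in CR3 than in all 3 groups, and against mCherry 24 were lower over all genes and 24 adjusted over the list alone. CDC20, the activator of the anaphase-promoting complex, went from 4131 ± 116 in mCherry to 2583 ± 74.8 (log2 fold changes -0.68, -0.84 and -0.75), and CCNB2 had log2 fold changes of -0.64, -0.73 and -0.65. The kinesin KIF20A (-0.59 against mCherry) and the survivin gene BIRC5 (-0.46) fell too. The list's median was -0.51, -0.66 and -0.61, with a largest camera adjusted p of 4.06e-17. The smallest adjusted p with an estimated correlation was 0.133.

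In the DNA replication and G1/S list, 18 of 23 genes were lower in all 3 comparisons, and 20 were lower against mCherry adjusted over the list alone. The ribonucleotide reductase subunit RRM2 fell from 7404 to 5133, and the replicative helicase subunit MCM7 had log2 fold changes of -0.39, -0.61 and -0.50. The largest camera adjusted p was 2.72e-09, and the smallest adjusted p with an estimated correlation was 0.133.

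MYC and the genes it is known to drive were lower. MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) stood at 1344 ± 35.2 in CR3 against 1900 ± 105 in mCherry, 2160 ± 76.8 in scramble and 2233 ± 114 in reverse, with limma adjusted p of 1.7e-06, 3.5e-08 and 1.8e-08. Of 20 MYC targets, 16 were lower in all 3 comparisons and 18 were lower against mCherry adjusted over the list alone. Among them, the transferrin receptor TFRC fell from 6805 to 4976, and the mitochondrial chaperonin HSPD1 from 20630 to 14740. The list's median was -0.31, -0.51 and -0.42, the largest camera adjusted p was 2.99e-10, and the smallest adjusted p with an estimated correlation was 0.0537.

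Transcripts for protein synthesis followed. Of 35 cytosolic ribosomal protein genes, 31 were lower in all 3 comparisons and all 35 were lower against mCherry adjusted over the list alone. RPLP0 fell from 35580 to 25330, and RPL14 had a log2 fold change of -0.43 against mCherry. The list's median was -0.31, -0.32 and -0.29, with a largest camera adjusted p of 4e-15 and a smallest adjusted p with an estimated correlation of 0.149. Of 24 genes for ribosome biogenesis and RNA polymerase I, 15 were lower in all 3 comparisons and 15 against mCherry adjusted over the list alone, among them the rRNA methyltransferase FBL (-0.42, -0.59 and -0.52) and NOP56. Their largest camera adjusted p was 4.46e-06, and the smallest adjusted p with an estimated correlation was 0.0821.

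Genes tied to large enhancers in colorectal cancer were lower as well. In the list of super-enhancer-associated genes, 11 of 17 fell in all 3 comparisons, and 12 were lower against mCherry both over all genes and adjusted over the list alone. TCF7L2, the main transcription factor of Wnt signaling in the gut, went from 3651 to 2304 ± 44.2 and the zinc finger factor KLF5 from 1434 ± 89.7 to 991.8 ± 16.8. SOX9, a factor of intestinal progenitor cells, had log2 fold changes of -1.01, -0.43 and -0.60. The list's median was -0.41, -0.32 and -0.34, with a largest camera adjusted p of 5.53e-05 and a smallest adjusted p with an estimated correlation of 0.102.

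Wnt target genes split. CD44 (ENSG00000026508, chromosome 11, 35138870 to 35232402), a hyaluronan receptor, fell from 5807 ± 105 to 3508 ± 154. The feedback inhibitor AXIN2 went from 413.4 ± 34.3 to 244.4 ± 19.8, and RNF43 and DKK1 were lower too. LEF1, a partner of beta-catenin, reached 66.6 in CR3, at least 22.6-fold above mCherry, and PROX1 reached 47.95 with a ratio of 147 (25.9 to 5840). The 16 members therefore held 4 decreases and 2 increases in all 3 comparisons, and 4 and 3 against mCherry adjusted over the list alone. The list was not called by camera (largest adjusted p 0.78). Its median was -0.09 and its mean 0.54 against mCherry, and camera's direction was downward.

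Immediate early genes and feedback genes of MAPK signaling also went both ways, with 4 of 24 higher and 7 lower in all 3 comparisons and 4 and 9 against mCherry adjusted over the list alone. JUN rose from 432.1 to 741.6 and EGR1 from 7920 to 11500, with EGR2 and EGR3 also higher. MYC and IER3 were among those that fell. Camera did not call the list (largest adjusted p 0.804). Its median against mCherry was 0.01 and its mean 0.03, whereas the test pointed downward.

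Metabolic and protein quality genes made up most of the other lists called lower. Of 17 glycolysis genes, 10 fell in all 3 comparisons and 13 against mCherry adjusted over the list alone. Lactate dehydrogenase LDHA went from 20450 to 12950 and the enolase ENO1 had a log2 fold change of -0.47 against mCherry. The largest camera adjusted p was 0.00205 and the smallest adjusted p with an estimated correlation 0.324. Nuclear-encoded oxidative phosphorylation genes had 9 of 30 lower in all 3, with 12 against mCherry adjusted over the list alone and a median of -0.10, -0.12 and -0.09. Camera gave at most 0.00795, and the smallest adjusted p with an estimated correlation was 0.259. Of 18 NRF2 targets, 10 fell in all 3 comparisons, led by the quinone reductase NQO1 (7778 to 5637), and 11 were lower and 1 higher against mCherry adjusted over the list alone. Their largest camera adjusted p was 0.000488 and the smallest adjusted p with an estimated correlation 0.0623.

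Of 29 proteasome genes, 18 were lower in all 3 comparisons and 22 against mCherry adjusted over the list alone, with PSMB1 at -0.30 and PSMD2 at -0.25 against mCherry. The largest camera adjusted p was 1.28e-07 and the smallest adjusted p with an estimated correlation 0.0824. Cytosolic chaperones held 11 decreases and 1 increase (HSPA4L) among 17 genes, and 14 and 1 against mCherry adjusted over the list alone. HSP90AB1 fell from 73920 to 54860. Here the largest camera adjusted p was 4.46e-06 and the smallest adjusted p with an estimated correlation 0.149. ER chaperones had 7 of 18 lower in all 3, 8 against mCherry adjusted over the list alone, with HSPA5 at -0.21 against mCherry. Camera gave at most 0.00953, and the smallest adjusted p with an estimated correlation was 0.149.

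Of 27 splicing factor and speckle genes, 15 were lower in all 3 comparisons and 1, CLK4, was higher, with 16 and 1 against mCherry adjusted over the list alone. HNRNPA1 fell by 0.41 on the log2 scale against mCherry. Camera gave at most 0.000142 as adjusted p, and the smallest adjusted p with an estimated correlation 0.295. Among 23 stress granule and P-body genes, 9 were lower in all 3 comparisons and FXR2 was higher, with 9 and 3 against mCherry adjusted over the list alone. The poly(A)-binding protein PABPC1 went from 47470 to 35090. The adjusted p of camera was 0.0225 or lower, and the smallest adjusted p with an estimated correlation 0.242.

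The split between higher and lower genes depends on the scaling. With library size alone, 2760 genes were higher and 925 lower in CR3 than in all 3 groups, and the median of all genes against scramble moved to 0.103. Under that scaling no list turned its direction, but the camera calls of stress granule genes (adjusted p 0.195, 0.088 and 0.0544), ER chaperones (0.0749 against mCherry and 0.0672 against reverse) and nuclear-encoded oxidative phosphorylation genes (0.0857 against reverse) were lost. The calls of RNA polymerase II subunits (0.0683) and of markers of embryonic kidney and neuron-like lines (0.0628) against scramble were lost too, and calls were gained for intestinal markers against mCherry (0.0436) and reverse (0.0486) and for senescence and lysosome genes against reverse (0.0336).

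Only 3 lists were called higher in CR3 in all 3 comparisons. Mesenchymal and fibroblast markers held 8 of 14 genes higher in all 3, and against mCherry 9 were higher and 1 lower adjusted over the list alone. VIM (ENSG00000026025, chromosome 10, 17228259 to 17237593), the intermediate filament of mesenchymal cells, went from 97.4 ± 8.97 to 764.4 ± 31.1. Its log2 fold changes were 2.96, 3.29 and 3.55. N-cadherin (CDH2) rose from 1.90 to 129.8 ± 13.9, COL5A1 from 2.39 to 146.7 and smooth muscle actin ACTA2 from 155.4 ± 9.24 to 475.4 ± 15.5. Members near 0 elsewhere can pass the filter through their CR3 reads alone, which can raise the share of 8 of 14. Other written members, among them COL1A2, COL3A1, LUM and DCN, were not tested. Without genes under 20 normalized reads in the 9 other libraries, all 17 lists that camera called, this one included, kept their call. SNAI1, a repressor of E-cadherin, went against the list, being lower against mCherry and scramble. The list's largest camera adjusted p was 8.05e-05. With an estimated correlation its adjusted p was 0.0472 against scramble, 0.0529 against mCherry and 0.059 against reverse. The fry test did not call the list in all 3 comparisons (largest adjusted p 0.231). Read with powers of 10 set without the group labels, which assumes that groups do not differ, VIM had a log2 fold change of -0.35 against mCherry.

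The p53 target list had 10 of 22 genes higher in all 3 comparisons, and against mCherry 11 were higher and 1 lower adjusted over the list alone. The sestrin SESN2 went from 505.6 to 878.3, SPATA18 from 4.33 to 118, and ZMAT3 and the cell death gene BAX were also higher. The classical targets CDKN1A (0.13, 0.09 and 0.14) and MDM2 (0.07, 0.06 and -0.01) did not pass the test in any of the 3. The largest camera adjusted p was 0.00335 and the smallest adjusted p with an estimated correlation 0.107.

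Histone genes were measured here from polyA RNA, in which most replication-dependent histone messages are poorly represented. Of the 8 tested, 4 were higher in all 3 comparisons and 6 were higher against mCherry adjusted over the list alone. H2BC12 rose from 1105 to 1543, and H2BC21 had log2 fold changes of 0.70, 0.89 and 1.09. The largest camera adjusted p was 0.00242 and the smallest adjusted p with an estimated correlation 0.149.

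Markers of other cell types were examined as a check on what the libraries contain. Of 19 epithelial junction and keratin genes, 5 were lower and 0 higher in all 3 comparisons by limma, with 5 and 1 against mCherry adjusted over the list alone. EPCAM fell by small amounts (-0.24, -0.25 and -0.23). Camera called that list against mCherry (0.0176) but not in all 3 (largest 0.126), and the adjusted p with an estimated correlation was 0.281. Of 6 tested markers of embryonic kidney and neuron-like lines, the neurofilament genes NEFM (0.348 to 147.6 ± 28.7) and INA (1.83 to 74.7) were higher and TUBB3 was lower in all 3 comparisons. Adjusted over the list alone, 3 were higher and 1 lower against mCherry. That list passed camera against scramble (0.0291, or 0.0628 with library size alone) and reverse (0.022) but not mCherry (0.0685). The adjusted p with an estimated correlation was 0.155 in each of the first 2. The fry test called that list in all 3 comparisons (largest adjusted p 7.44e-05). Endothelial markers had 1 of 5 higher in all 3, TIE1, with 1 against mCherry adjusted over the list alone and a largest camera adjusted p of 0.691. The 5 tested intestinal differentiation markers had no member changed in all 3 comparisons by limma and a largest camera p of 0.511, although 1 was lower against mCherry, also adjusted over the list alone. Only 2 immune markers were measured well enough, too few to test.

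Several lists close to condensate biology were not called in all 3 comparisons. Of 32 Mediator subunits, MED23 was higher and MED30 lower, and the largest camera adjusted p was 0.72. Among 24 elongation and BET coactivator genes, CDK7 and NELFB were lower (largest adjusted p 0.99), and among 12 RNA polymerase II subunits 2 were lower, POLR2H and POLR2E (0.148). Against mCherry these 3 lists held 2 higher and 2 lower, 2 higher and 5 lower, and 0 higher and 2 lower genes by limma adjusted over the list alone. RNA polymerase II subunits passed camera against scramble (0.0223, or 0.0683 with library size alone), where the adjusted p with an estimated correlation was 0.155.

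Interferon-stimulated genes had 3 higher (OASL, HERC5 and STAT2) and 1 lower (OAS3) of 22 in all 3 comparisons, and 1 and 1 against mCherry adjusted over the list alone. Camera called them against scramble (0.0113) and reverse (0.00324) but not mCherry (0.147), and the adjusted p with an estimated correlation was 0.259 and 0.21. ATF4 targets had 2 higher and 8 lower of 23 (largest camera adjusted p 0.0687), with a median of -0.11, a mean of 0.09 and a downward test against mCherry. Against mCherry 3 were higher and 9 lower adjusted over the list alone. Camera called them against scramble (0.0108) and reverse (0.0107), with adjusted p of 0.246 and 0.242 with an estimated correlation. Cholesterol synthesis genes had 6 of 24 lower in all 3 (0.134), and 10 lower against mCherry adjusted over the list alone. Camera called them against mCherry (0.00429) and reverse (0.00204), with adjusted p of 0.353 and 0.321 with an estimated correlation.

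TGF-beta targets had 4 higher and 1 lower of 15 (0.181), and 5 and 2 against mCherry adjusted over the list alone. The type IV collagen genes COL4A1 (3.66 to 136.1) and COL4A2 (2.10 to 350.2 ± 27) and the inhibitor SMAD7 (8.97 to 51.7) were among those that rose. With powers of 10 set without the group labels, SMAD7 was at -0.69 against mCherry. YAP/TEAD targets had 2 higher and 2 lower of 17 (0.54), the same numbers against mCherry adjusted over the list alone, and TEAD1 itself had log2 fold changes of -0.65, -0.71 and -0.52. NF-kB targets had SOD2 as the single gene lower of 13 (0.88), 1 lower adjusted over the list alone against mCherry, and a median of 0.07 with a downward test. Senescence and lysosome genes had 3 higher and 1 lower of 19 (0.488), and 5 and 2 against mCherry adjusted over the list alone. The lower one was the lamin gene LMNB1 (2726 to 1949).

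Hypoxia genes had 2 of 19 higher in all 3, LOX and the glucose transporter SLC2A3. Camera called the list lower against mCherry only (0.00399, median -0.32, mean -0.08, adjusted p 0.422 with an estimated correlation), where 12 were lower and 2 higher adjusted over the list alone. The 13 mitochondrially encoded mRNAs were not called against mCherry (0.311). They were higher in CR3 than in scramble, with a median of 0.48 and 12 genes over all genes and adjusted over the list alone (4.16e-06, adjusted p 0.259 with an estimated correlation). Against reverse the median was 0.27, with 10 genes by both adjustments (0.00194, adjusted p 0.382 with an estimated correlation).

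In total, camera called 14 lists lower and 3 higher in all 3 comparisons out of 35 tested. With an estimated correlation 0 were called in all 3, and 5 lower and 2 higher had an unadjusted p under 0.05 in each. The fry test asks whether a list's genes move one way and does not compare them with other genes. It called 20 lists, of which 16 were lower and 4 higher. The mesenchymal list was not among them.

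**Figure D4:**
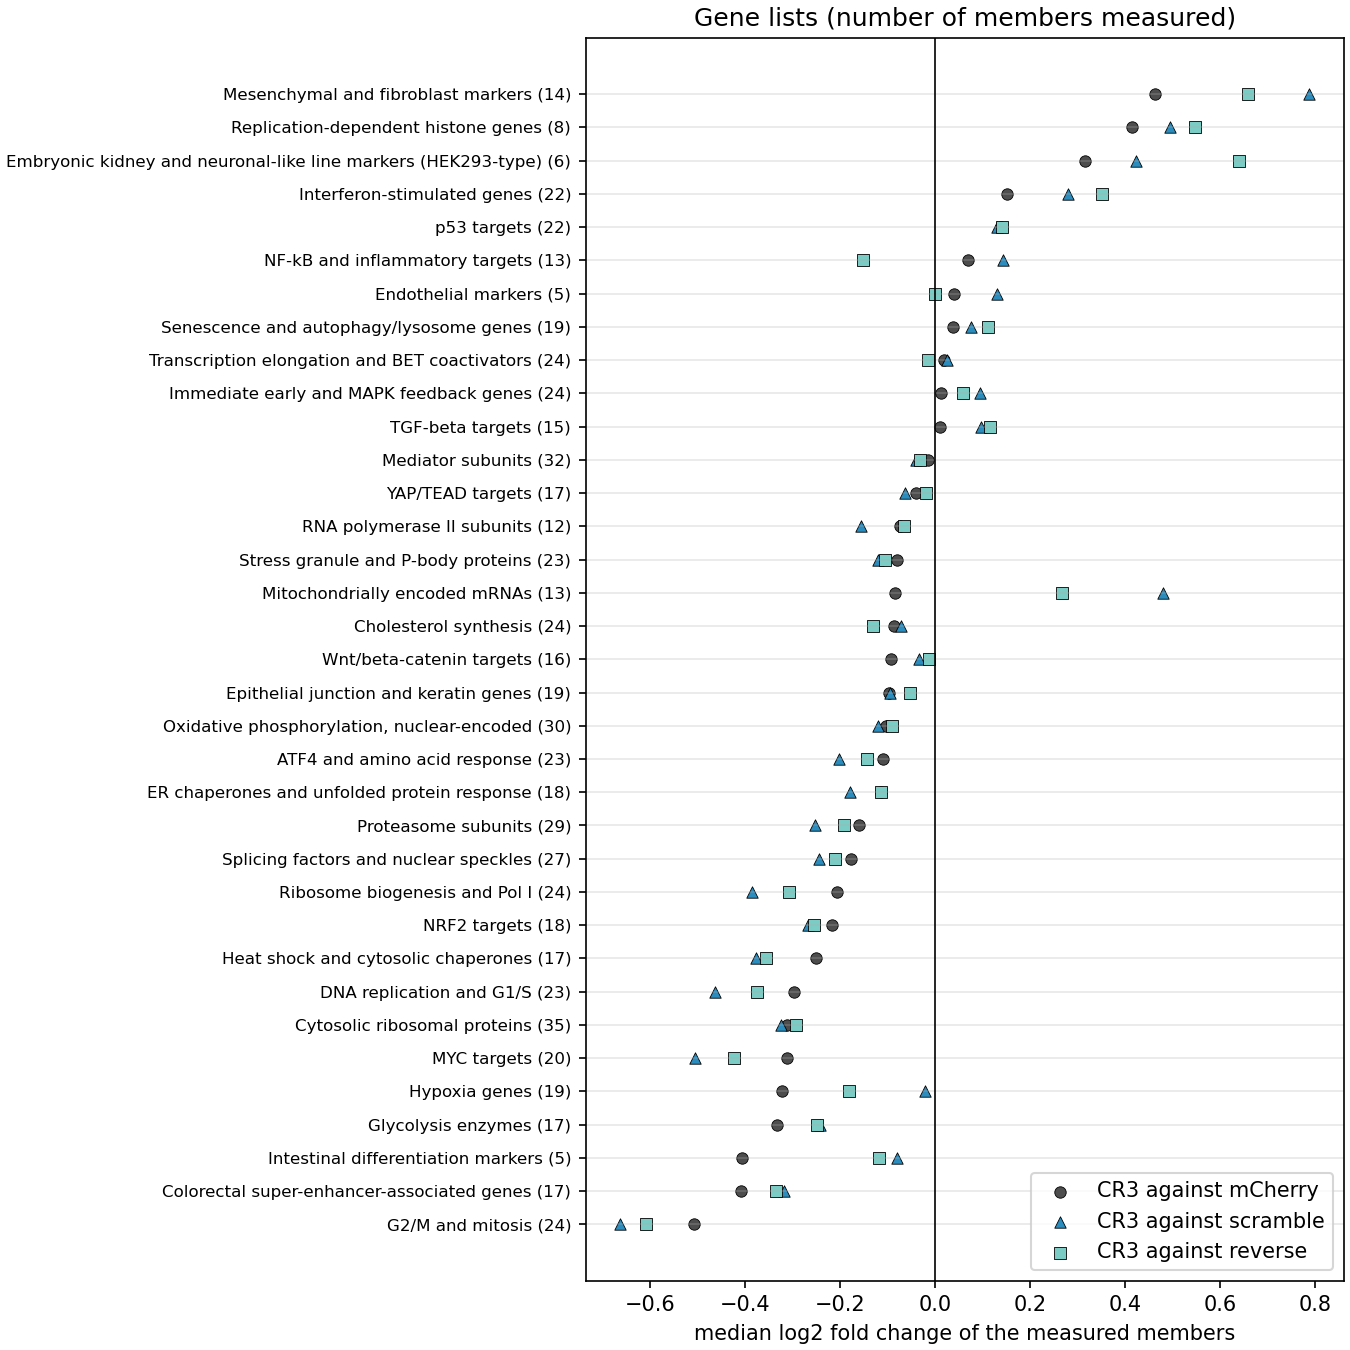
Each mark is the median log2 fold change of a gene list (horizontal axis) in CR3 against mCherry, scramble or reverse, with lists on the vertical axis. G2/M and mitosis genes have medians of -0.51, -0.66 and -0.61, and mesenchymal markers of 0.46, 0.79 and 0.66.

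Against mCherry alone, the comparison of the peptide with the control protein, 4408 genes differed, 2174 higher and 2234 lower, of which 760 and 73 by more than 2-fold. BCAT1, an enzyme of branched-chain amino acid breakdown, reached 198.6 ± 25.8 with a ratio of 610 (109 to 24100) over 1 read in mCherry. Some of the decreases were shared by scramble and reverse. INIP, part of a single-stranded DNA binding complex, stood at 1717 ± 59.1 in mCherry, 788.2 ± 29.4 in CR3, 876.2 ± 2.27 in scramble and 855.2 ± 35.8 in reverse. The cilium-related gene DLEC1 stood at 50.6 in mCherry, 16.2 in CR3 and about equally low in scramble (7.97) and reverse (8.12). GPR15 (-1.06), the hypoxia gene ANKRD37 (-1.09), COL17A1 (-1.22), JMJD1C-AS1 (-1.14) and AACSP1 (-1.11) were also among the 10 largest decreases of genes with at least 1 CPM on average and no overlap between libraries of both groups. With library size alone the call became 3573 higher and 1257 lower, and against a minimum fold of 1.5, 690 genes passed.

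Against scramble, 5836 genes differed, 2948 higher and 2888 lower, of which 845 and 48 by more than 2-fold. Under the rule for named genes, the largest increases were XIST, LAPTM5, UCHL1, LUZP4 and IRS4. The 5 largest decreases under that rule were genes that stood highest in scramble. SMIM18 and the muscle myosin MYH13 had no reads in CR3. The giant sarcomere protein NEB stood at 234.2 ± 30.6 in scramble and 23.4 ± 10.1 in CR3, and the membrane skeleton gene ANK1 at 281.6 and 76.9. RASGRF2 had a log2 fold change of -2.78, which became 0.5 with powers of 10 set without the group labels. With library size alone 4502 genes were higher and 1793 lower, and 717 passed a minimum fold of 1.5.

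Against reverse, 5192 genes differed, 2614 higher and 2578 lower, of which 810 and 58 by more than 2-fold. LAPTM5, LUZP4, NID1, IRS4 and XIST led the increases among genes that met the rule for named genes. The largest decreases among them were UGT2B7, KCNMB2, TEK, SI and DOCK2, genes that were near 0 in CR3 and present in reverse. With library size alone 4058 genes were higher and 1539 lower, and 709 passed a minimum fold of 1.5.

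The 3 comparisons share the CR3 libraries, which makes their chance values correlate. CR3 against mCherry and CR3 against scramble had 1882 genes higher and 1849 lower in both, where independent lists would share 415.3 and 418.1. Simulations without effects, which hold hardly any calls by design, gave a mean of 0 in each direction by limma. The covariance of the log2 fold changes of both comparisons was 0.88, against 0.0187 in simulations without effects. The pairs with reverse gave 1802 higher and 1846 lower with mCherry, and 2206 and 2217 with scramble.

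Scramble against mCherry asked what the scramble construct changes by itself, and 235 genes differed. Of these, 117 were higher and 118 lower, 26 and 57 of them by more than 2-fold. SMIM18 (ENSG00000253457), a small membrane protein gene, reached 325.8 ± 13.6 normalized reads in scramble with no reads in any other library, at least 110-fold above mCherry (limma adjusted p 2.01e-11). MYH13 stood at 176.7 ± 7.22, at least 59.9-fold higher. The fibrillin gene FBN2 went from 3.51 ± 1.19 to 561.7 ± 26.1 and was also present in CR3 at 257.8 ± 80.2. CHRDL1, a secreted BMP antagonist, was at least 19.8-fold higher, and RASGRF2, an exchange factor for RAS, went from 4.57 to 201.6 ± 26.9.

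Mitochondrially encoded mRNAs were lower in scramble than in mCherry, 12 of 13 by both adjustments, over all genes and adjusted over the list alone. MT-CYB fell from 37000 ± 2010 to 22610 ± 3310 (log2 fold change -0.72), MT-CO2 by 0.71 and MT-ND5 by 0.68, and MT-ND6 did not pass the test. The list's median was -0.59 and its camera adjusted p 6.57e-24, and the adjusted p was 0.0828 with an estimated correlation. Ribosome biogenesis genes were higher by small amounts, with a median of 0.21, a camera adjusted p of 4.88e-17 and an adjusted p of 0.0743 with an estimated correlation. Over all genes 4 passed (POLR1B, NOLC1, UTP4 and NAT10) and 18 adjusted over the list alone. MYC targets (median 0.17, 3 and 16 adjusted over the list alone, camera 1.27e-12, adjusted p 0.0743 with an estimated correlation) and DNA replication genes (0.17, 1 and 16 adjusted over the list alone, 2e-13, adjusted p 0.188 with an estimated correlation) were also higher. Camera called 9 lists higher and 5 lower in this comparison, the higher ones including G2/M and mitosis (median 0.15, camera 1.32e-10), proteasome (0.10, 1.2e-08) and cytosolic chaperone genes (0.12, 9.2e-06), and with an estimated correlation 0 passed. Hypoxia genes were lower, with a median of -0.34 and 2 genes over all genes, ANKRD37 and BNIP3L, and 12 adjusted over the list alone (camera 1.6e-08, adjusted p 0.288 with an estimated correlation).

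The count of 235 depended on which and how many libraries entered the fit. It became 599 without mCherry replicate 3, 129 and 110 without mCherry replicates 1 and 2, and 114, 118 and 99 without scramble replicates 1, 2 and 3. It was also 80 when only the compared groups were fitted, 134 without the CR3 libraries and 57 against a minimum fold of 1.5.

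Reverse against mCherry called 98 genes, 39 higher and 59 lower, with 32 and 43 by more than 2-fold. DOCK2, an exchange factor best known from blood cells, reached 211.4 ± 34 in reverse and was at least 71.6-fold above mCherry, where it had no reads (limma adjusted p 2.63e-10). TEK, the angiopoietin receptor of endothelial cells, stood at 212 ± 39.3 with a ratio of 329 (90.7 to 2720) over 2 reads in mCherry. UGT2B7, a glucuronidating enzyme, reached 141.2 ± 9.67, at least 47.8-fold higher, and the potassium channel subunit KCNMB2 115.5 ± 11.5, at least 39.1-fold higher. Sucrase-isomaltase SI, a digestive enzyme of the small intestine, went from 1.12 to 100.1 ± 9.48. Mitochondrially encoded mRNAs had a median of -0.36, with 5 lower over all genes (among them MT-CYB at -0.49) and 12 lower and 1 higher adjusted over the list alone. Camera gave 3.72e-16 for them, and the adjusted p was 0.241 with an estimated correlation. It called 6 lists higher and 5 lower, the higher ones including MYC targets (median 0.11, camera 2.01e-09) and ribosome biogenesis genes (5.55e-09), each with 0 genes over all genes, 5 adjusted over the list alone and an adjusted p of 0.241 with an estimated correlation. Upward medians in scramble and reverse enter the comparisons of CR3 with those groups, although few of the genes passed singly. MYC targets had medians of -0.51 and -0.42 in CR3 against scramble and reverse, and of -0.31 against mCherry. The count became 185 without mCherry replicate 3, 48 among genes with at least 1 CPM on average, and 60 when only the compared groups were fitted.

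Of the 59 genes lower in reverse than in mCherry and the 118 lower in scramble, 53 were the same genes, where independent lists would share 0.5. Both were higher at 2 genes, where 0.3 would be shared, and 0 genes went in opposite directions by limma. Simulations without effects drew new libraries with noise independent between genes, and gave a mean of 0 shared calls in each direction. Hardly any call can arise there, so that 0 sets no yardstick for the 53. Among genes with at least 1 CPM on average, the overlap was 24, of which 22 were lower in both, with a correlation of 0.383. RYR2, a calcium release channel, stood at 17.4 ± 3.44 in mCherry, 0 in scramble and 1.02 in reverse. PCDH9 stood at 19.1 in mCherry and below 1 in both. MGAT3 went from 17.04 to 1.17 and 0.347, CDYL2 from 49.8 ± 1.29 to 6.17 and 6.77, and DLEC1 had a log2 fold change of -2.51 in both. MAP9, another of the named decreases in scramble, stood at 5.91 in mCherry and 0 in scramble, and at 2.65 in reverse with an adjusted p of 0.461. In CR3 some of these genes were present, at 202.2 for RYR2, 68.3 for PCDH9, 102.6 for MGAT3, 176 for CDYL2 and 112.3 for MAP9. They do not stand for the 53 shared decreases, of which 34 were also lower in CR3 than in mCherry. At those 34 genes mCherry stood above all 3 other groups. With powers of 10 set without the group labels, CDYL2 was at 0.16 in scramble and 0.37 in reverse, DLEC1 at 0.66 in reverse, and RASGRF2 at -1.18 in scramble.

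Both comparisons use the same mCherry libraries, which makes their log2 fold changes correlate without any effect. The Pearson correlation of the log2 fold changes across genes was 0.537 against 0.501 in simulations without effects, and the covariance 0.0675 against 0.0186. With 3 control libraries they could not be split, and part of the excess over independent lists may come from them.

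Reverse against scramble set these 2 constructs against each other. Of 71 genes, 44 were higher and 27 lower, 35 and 25 of them by more than 2-fold. The largest differences under the rule for named genes were mostly genes near 0 in 1 of both groups, namely DOCK2 (at least 76.3-fold), TEK (at least 76.5-fold), UGT2B7 (at least 51-fold), KCNMB2 (at least 41.7-fold) and SI (at least 36.1-fold) in reverse, and SMIM18 (at least 110-fold), MYH13, FBN2, CHRDL1 (at least 19.8-fold) and RASGRF2 in scramble. The RASGRF2 difference of -5.01 became 1.36 with powers of 10 set without the group labels. Among genes with at least 1 CPM on average 34 passed, and 46 passed a minimum fold of 1.5.

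Each construct was carried by its own cells, so a difference between constructs and a difference between the cell populations that carry them cannot be separated. Whether the 3 libraries of a group came from separate cultures is not given in the sources used here, and the p-values then measure only the spread between these samples, which may be technical.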

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

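Of the tests in this part, those on powers read too low, on a second cell line, on germline genes and on dilution were chosen after the results were seen. The others were set before.

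Scramble and reverse differed from each other at 71 genes in limma's test of the difference itself. The 10 given here are the 5 largest in each direction under the rule for named genes. Only 1 of both groups carried them in quantity. Against mCherry, the reverse effect exceeded the scramble effect by 7.72 (log2) for DOCK2, 7.72 for TEK, 7.15 for UGT2B7, 6.86 for KCNMB2 and 6.66 for SI. The difference was -8.35 for SMIM18, -7.16 for MYH13, -6.89 for FBN2, -5.90 for CHRDL1 and -5.01 for RASGRF2. Where 1 group had no reads these fitted values are set by the pseudocount.

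The first pattern weighed is the 608 genes at least 2-fold higher in CR3 and under 20 normalized reads on average over the 9 other libraries. A power of 10 read too high in CR3 is argued against, since 602 of 608 (99%) stayed at least 2-fold above the other groups with the smallest CR3 counts their digits allow. A power read too low in the other groups is argued against for the 386 genes with a library of 0 reads or a kept mark in each of them, as in 371 (96.1%) that library was too low for a group at 0.5 of CR3. It stays open for the remaining 222, of which 123 stayed at least 2-fold higher with powers of the other groups set without group labels, a reading that assumes no group difference. Switching peculiar to the cells that carry CR3 stays open. The other groups held 28, 16 and 20 such genes, but that difference is the pattern itself and excludes nothing. RNA of an embryonic kidney line stays open, since only 6 of its listed markers were tested and their median was 0.32, with 2 higher in all 3 comparisons (NEFM at 147.6 and INA at 74.7, which passed the filter only through their reads in CR3) and 1 lower. The fry test called these markers in all 3 comparisons (largest adjusted p 7.44e-05). XIST, outside that list, had log2 fold changes of 7.65, 9.21 and 7.83 in CR3 against mCherry, scramble and reverse. No test here shows whether all CR3 cells are HCT116. Loss of promoter methylation silencing stays open too. Of 35 germline genes, 6 were tested, and the 5 that were higher (LUZP4, MAGEA6, MAGEA12, TEX15 and ASZ1) passed the filter only through their reads in CR3, so their share of the tested genes decides nothing. MAGEA3 stood at 1742 in mCherry and 1623 in CR3, and MAGEA reads can be shared between near-identical copies.

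The second pattern is the 64 genes at least 2-fold higher in 1 of mCherry, scramble and reverse than in all 3 other groups and under 20 normalized reads on average over the 9 other libraries. Some had reads in other groups as well, such as NEB, at 234.2 in scramble and 20.9 in reverse. A power read too high is argued against, since all 64 stayed at least 2-fold higher with the smallest counts. A power read too low in the other groups is argued against for 42 genes by the same kind of library (39 of them, 92.9%). It stays open for the remaining 22, of which 10 stayed at least 2-fold higher with powers set without group labels, and RASGRF2 and DLEC1 reversed there in comparisons with mCherry (-1.18 in scramble and 0.66 in reverse). Local events that switch on neighbouring genes, such as the insertion of the construct, cannot be told apart from scattered switching. Of the 64, 2 had another within 200 kb, equal to the 95th percentile of 1000 random draws (2, with a median of 0), too few to decide.

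The third pattern is the 1729 genes lower in CR3 than in all 3 groups. Dilution by cells that lack the transcripts of both the mitosis and epithelial lists is argued against, as it would lower both alike. The mitosis list had a median of -0.51 (interval -0.56 to -0.46) whereas the epithelial list had -0.10 (-0.26 to -0.03). Cells that lack some transcripts and keep others could lower the lists unequally, so dilution by such cells stays open. Removal of a trend with transcript length left the median at -0.29 over 1713 genes. Removal of a trend with expression level moved it from -0.29 to -0.24 over 1728 genes, 97.2% still below 0. The trends removed were thus small beside these decreases. However, the genes were chosen for being lower in the same data, which favors a median below 0 after removal. Whether such trends add to the calls therefore stays open. Against mCherry the median was 0.30 in the 10% of genes with the lowest mean and -0.11 in the 10% with the highest. The effect of the CR3 peptide itself, the biological explanation, stays open for all these genes, because the peptide and the cells that carry it change together and no test here separates them.

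Whether other groupings of the libraries give as many calls was also counted. For genes changed in CR3 against all 3 groups, 1 of 100 splits, the real one, reached 3425. The highest other gave 0 by limma and 1066 at an unadjusted p under 0.05. The powers of 10 had been set with the real groups, which can favor the real split. Splits that mix CR3 libraries with others also widen the spread within groups, so few calls could arise in them. No conclusion about chance is therefore drawn from this count, and a chance difference between the cell populations was not tested. For gene lists, 1 of 100 splits reached 17, with 15 as the highest other. Another grouping thus called nearly as many lists, so no conclusion is drawn from the number called. With an estimated correlation camera called 0 in all 3 comparisons. In each comparison of 2 groups there are only 10 splits, too few for a share under 0.05. The real split and the highest other gave 4408 and 123 for CR3 against mCherry, and 5922 and 2799 at an unadjusted p under 0.05. For the others the real splits gave 5836 (CR3 against scramble), 5192 (CR3 against reverse), 235 (scramble against mCherry), 98 (reverse against mCherry) and 71 (reverse against scramble), and the highest other gave 0 by limma in each. At an unadjusted p under 0.05 those highest others gave 597, 1151, 1560, 2748 and 898, against 7144, 6668, 2237, 1465 and 1106 in the real splits.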

How the results depend on the processing

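The tests with TMM, other pseudocounts, voom, powers of 10 without group labels, ambiguous genes kept, and without low genes or CR3 libraries were chosen after the results were seen. The edgeR, DESeq2 and glmTreat tests of the plan were not run, as the values are not counts, and the deposited size factors stand for RLE.

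No named gene reversed in direction under another scaling, filter, pseudocount, the block, voom or any left-out library. No list reversed under another scaling, the block, without low genes or without any library, and other settings were not run on lists. Total counts for CR3 moved by under 1.5 times in those settings. With library size alone, however, the lower genes went from 1729 to 925 (all 3) and from 2234 to 1257 (mCherry). Without low genes, the higher genes went from 1696 to 1098 (all 3), and 1720 were lower. With a minimum fold of 1.5 the total counts were 690 (mCherry), 717 (scramble), 709 (reverse) and 593 (all 3, 592 of them higher). They were 57, 59 and 46 for scramble and reverse against mCherry and reverse against scramble, and 112 of 240 named calls stayed. Scramble against mCherry gave 80 with the compared groups only and 134 without the CR3 libraries. Reverse against mCherry gave 48 at 1 CPM or more, 60 with the compared groups only and 61 with powers set without group labels. Reverse against scramble gave 34 at 1 CPM or more, and the overlap of scramble and reverse effects 24 in place of 55 (r = 0.383). Fewer genes or samples enter the CPM and compared-group settings, and other causes were not tested. With an estimated correlation 0 lists were called by camera in all 3 comparisons (7 at an unadjusted p under 0.05, 20 by fry).

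Same-numbered libraries did not deviate together (mean correlation -0.024, range -0.134 to 0.065; other numbers 0.012), so the numbers do not pair them. With the replicate block, scramble against mCherry gave 139. The block moved no other count by over 1.5 times.

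Leaving out each library in turn gave 3301 to 4363 genes for CR3 against mCherry, 4734 to 5483 against scramble, 4090 to 5010 against reverse and 2625 to 3301 against all 3. It gave 99 to 599 for scramble against mCherry (599 without mCherry replicate 3, 99 without scramble replicate 3), 79 to 185 for reverse against mCherry (185 without mCherry replicate 3) and 59 to 65 for reverse against scramble.

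Powers set without group labels assume that groups do not differ. There 8 named calls reversed, and 30 lost their call. VIM (-0.35) and SMAD7 (-0.69) reversed in CR3 against mCherry. RASGRF2 reversed in CR3 against scramble (0.5), in scramble against mCherry (-1.18) and in reverse against scramble (1.36). CDYL2 in scramble (0.16) and reverse (0.37) and DLEC1 in reverse (0.66) reversed against mCherry. Depth limits genes near 10 reads, where 1 read moves a value most.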

Other observations

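The genes and summaries in this part were chosen after the results were seen, and no tests were planned for them.

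The mCherry libraries also carried genes of their own. Of 28 genes at least 2-fold higher in mCherry than in all 3 others, all 28 averaged fewer than 20 normalized reads over the 9 other libraries. The stretch-activated channel PIEZO2 averaged 72.5 ± 11.8 there and 0.32 at most in another group. The synaptic vesicle gene SV2C averaged 58.1 ± 22.6, the anion exchanger SLC26A3 35.1 ± 5.65 with no reads in any other group (at least 12.2-fold above CR3), and xanthine dehydrogenase XDH 28.7 ± 2.87. Scramble had 16 such genes and reverse 20.

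Enzymes of DNA and histone methylation were also read. In CR3 against mCherry DNMT1 had a log2 fold change of -0.25, EZH2 of -0.27, DNMT3A of 0.32 and TET1 of 0.67. Germline genes other than LUZP4 that were higher in CR3 included MAGEA6 (2.82 in mCherry, 201.5 ± 4.65 in CR3), MAGEA12 (0 and 122.3 ± 14.1), TEX15 (2.39 and 54.1 ± 11.9) and ASZ1 (0 and 25.2 ± 5.35).

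The 10% of genes with the highest mean over all libraries had a median log2 fold change in CR3 of -0.11 against mCherry, -0.13 against scramble and -0.12 against reverse. The 10% with the lowest mean went the other way, with 0.30, 0.36 and 0.33. Some lists called lower had medians near those of the highest genes, such as nuclear-encoded oxidative phosphorylation (-0.10, -0.12 and -0.09). Others had larger ones, such as the mitosis list (-0.51, -0.66 and -0.61). Whether level contributes to the list calls was not tested. Medians by chromosome against mCherry stayed within -0.08 (chromosomes 8 and 18) and 0.07 (chromosomes 22 and X).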
